A study of Homo sapiens with 16 samples.

How the data were processed

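Gene expression was measured by RNA sequencing in 16 human lymph node samples, taken from 8 patients at baseline and again after 24 weeks of treatment with MGN1703, an agonist of Toll-like receptor 9 (TLR9). TLR9 is the endosomal receptor for unmethylated CpG DNA and in humans is found mainly in B cells and plasmacytoid dendritic cells. Per the labels' protocols, total RNA was purified with a column kit, cDNA was made from a low input with SMART-Seq v4, a full-length method primed on poly(A) tails, and libraries were made with Nextera XT, a transposase kit that does not mark strand. No untreated patients sampled at the same 2 times are among the samples, so treatment and time go together.

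The deposited table holds 1 value per Ensembl gene ID and library. The values were taken to be expected (estimated) counts, since the submitters' processing notes list RSEM 1.2.31, Bowtie2, DESeq2 and the build hg38, without saying what each was used for. All deposited values are whole numbers of 0 or more, none of the 46002 gene IDs carries a value with a fraction, and the totals differ between libraries, so the expected counts were used as deposited and rounding changed nothing. Which annotation the authors counted against, and whether they rounded, is not given in the sources used here. RSEM shares reads that map to several genes among them, so values of near-identical genes are estimates. Reads are not separated by strand, so a gene and an overlapping antisense gene cannot be told apart.

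Gene names, positions, exon length and exon GC content came from GENCODE v29 on GRCh38, the assembly also called hg38, which named 42553 of the 46002 IDs. The other 3449 IDs held 0.0466% of all counts and kept their ID as name. A total of 18827 IDs had no count in any library. XIST, TSIX, Y-linked genes and HLA genes outside a fixed MHC class II list were neither tested nor named. These 156 IDs held 0.915% of counts and stayed in the library sizes. Positions are 1-based.

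Genes were filtered with filterByExpr at its default minimum count of 10, which left 13046 genes. They were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the patient as a block and the group as the tested term. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. Fold changes are log2 values of MGN1703 minus baseline with their standard error (SE). Levels are CPM (counts scaled to the library size times its TMM factor) as mean ± SD.

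A set of 40 gene lists was fixed from textbook knowledge before the data were examined. They covered interferon and TLR9 signalling, B and T cell types, myeloid and stromal cells, other tissues a biopsy could hold, and stress, ribosomal and mitochondrial genes. Of these, 36 had at least 3 tested members. Each list was tested with camera of limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01). Camera compares the genes of a list with the other genes. Each list was also tested with an exact sign-flip permutation test of the change of its mean log2 CPM over the 8 pairs. That test has 256 sign patterns and a smallest p of 0.0078. After adjustment over 36 lists, no list can pass unless at least 6 do, so a single changed list cannot pass alone. Immunoglobulin measures and correlations of list changes were tested by exact permutation too.

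The named genes followed a rule fixed in advance. Among genes past the threshold with a mean CPM of at least 1 and the same direction in at least 7 of 8 pairs, it takes the 12 with the largest fold in each direction. It adds 28 fixed genes, up to 4 members with the smallest p of each list past a list test, and members past the threshold when adjusted over the list alone. P2RY8, IL3RA and GLYCAM1, members of 3 lists, were not analysed here. A further 5 genes that the rule names are not reported singly and are left out of the counts of named genes, but count as members of their lists. VCAM1 and CD14 lie outside the rule and were named after their values were seen.

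The pairing comes from the labels, which give the same patient at both times. As a check, the deviations of the 2 libraries of a pair from their group means correlated at between 0.144 and 0.668 (median 0.387) over tested genes, with 8 of 8 pairs over 0.1. Libraries of different pairs had a median correlation of −0.0692. In 4 of 8 pairs the own partner gave the highest correlation. No 2 libraries were copies of each other, the smallest chi-square per degree of freedom between 2 libraries being 16.0.

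Totals ran from 6739533 to 18041186 counts per library. The steps were tested on simulated data made from the means and library sizes of these 13046 genes and 8 pairs. With the block, edgeR recovered 19.4% of genes changed 1.5-fold, 46.3% of those changed 2-fold and 92.4% of those changed 4-fold, and 6 of its 111 calls were unchanged genes. When a GC trend was added to 1 group of the simulated libraries, 925 of 1059 calls were unchanged genes, and after the GC and length correction used here 4 of 113 were. The added trend was the same in each library of that group and linear in the GC values that the correction uses. Its removal was thus largely fixed in advance. In the data the Spearman rho of fold with GC content ran from 0.155 to 0.463 between pairs, which the simulation did not imitate. A list shifted by 0.8 on the log2 scale was found by camera and not by the exact test. The simulated genes were drawn independently, while the shifted list, type I interferon response, had an estimated correlation of 0.753 in the data. The simulation thus does not show how camera behaves on correlated genes. With only 1 list shifted, the exact test had almost no way to pass.

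The groups, the tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives fixed in advance were other normalizations, other filters, DESeq2 1.42.0, limma-voom with and without library weights, no block, fry, an estimated inter-gene correlation, immunoglobulin genes left out and each pair left out. Others were chosen after seeing the data: a correction for GC content and exon length (splines with 5 degrees of freedom per library) with the block, thinning both libraries of a pair to the smaller total, leaving out 2 pairs that hold a library with over 15% mitochondrial ribosomal RNA, leaving out mitochondrial genes, and a robust prior. Immunoglobulin variable and constant genes belong to families of similar sequence, and their counts are uncertain where reads fit several members.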

Results

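Lymph node RNA from 8 patients was sequenced at baseline and after 24 weeks of MGN1703, a DNA-based agonist of the pattern receptor TLR9, giving 8 libraries in each group. Baseline totals ran from 6739533 to 12182672 counts and MGN1703 totals from 10368497 to 18041186 counts. The MGN1703 library was the deeper of the pair in 8 of 8 patients, by 3322445 ± 2649756 counts (SD, n = 8 pairs, exact sign-flip p = 0.0078). More genes were detected after treatment, 19256 ± 518 against 18450 ± 650 (SD, n = 8, higher in 7 of 8 pairs, exact p = 0.0156). Mitochondrial mRNA took 5.97% ± 2.55 of counts at baseline and 3.15% ± 2.05 after treatment (SD, n = 8, lower in 7 of 8 pairs, exact p = 0.0156), and mitochondrial ribosomal RNA took 9.15% ± 3.57 and 7.32% ± 5.36 (exact p = 0.3125). No batch is given in the labels, so these library differences go with the treatment and cannot be separated from it by a within-batch value.

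The comparison of the treated with the baseline node of each patient asks, after the series title, how B cell differentiation and function in the node differ under a TLR9 agonist. Lists of interferon-stimulated, early response and heat shock, and pan B cell genes rose by at least 1 of 2 list tests, and lists of naive T cell, conventional dendritic cell, ribosomal protein and mitochondrially encoded genes fell by at least 1. None of these lists passed camera with an estimated correlation (adjusted p = 0.686 with an estimated correlation). Of 13046 genes tested with edgeR, 4463 changed, 2376 of them higher and 2087 lower, and 1159 changed at least 2-fold, 948 higher and 211 lower. In 2580 genes all 8 pairs moved the same way, against 0.781% of genes expected by chance. The 24 genes with the largest folds held 7 interferon-stimulated genes among the 12 that rose most, with FOS, HSPA6, HSPA1B and the histone genes HIST2H2AA3 and HIST2H2AA4. The 12 that fell most held FCER1A of dendritic and mast cells, CD207 of dendritic cells, CMA1, the mast cell chymase, and LYVE1, the hyaluronan receptor of lymphatic vessels. They also held CDH17, FABP3 and TSPAN7, the last of which did not pass after GC and length correction (−2.14 ± 0.77, SE), as well as AC010733.2, AC009148.1, AL358781.1, AC008147.2 and ENSG00000281017, which have clone names or no name and whose identity is uncertain. HIST2H2AA3 with HIST2H2AA4, and HSPA1A with HSPA1B, are near-identical copies, so the share of each within the pair is uncertain.

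The count and its direction depended on the fit. Without the block 1306 genes passed (987 higher, 319 lower). Scaling by library size alone moved the median of all folds by 0.19 and gave 3103 higher and 512 lower, so that 85.8% of calls were higher against 53.2% with TMM. Folds rose with exon GC content, from a median of −0.345 in the 283 genes with the lowest content to 0.79 in 1042 GC-rich genes, with a Spearman rho of 0.479 across 12987 genes, which are not independent replicates. The relation was positive within 8 of 8 pairs (rho 0.155 to 0.463). With the GC and length trend of each library removed, in the fit with the block, the median of all folds was 0.048, against 0.0047 before. The median of the differences in fold, gene by gene, was 0.14. In that fit 2808 genes passed, 67.6% of them higher. Of these, 2017 were also called without the correction, all in the same direction.

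**Figure D1:**
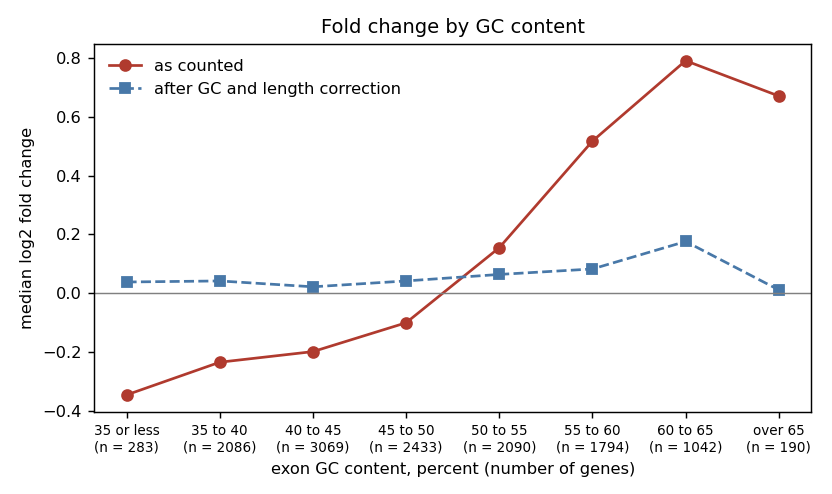
Median log2 fold change (y axis) of the tested genes, grouped by exon GC content in percent (x axis, with the number of genes), as counted (red circles) and after the GC and length correction (blue squares). The medians as counted run from −0.345 to 0.79, and those after correction from 0.0116 to 0.176.

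Type I interferon response genes were higher in the node after 24 weeks in 8 of 8 patients. The mean log2 level of the list, made of genes that type I interferon is known to induce, rose by 1.76 ± 0.98 (SD, n = 8 pairs, exact adjusted p = 0.0313). Of its 35 members 30 rose and 5 did not pass, with 31 higher when adjusted over the list alone. IFI44L (chromosome 1, 78619922 to 78646145) went from 19.2 ± 11.2 to 356 ± 207 CPM (SD, n = 8), a log2 fold of 4.16 ± 0.51 (SE, adjusted p = 0.000686). ISG15, a ubiquitin-like protein (chromosome 1, 1001138 to 1014540), went from 8.59 ± 5.15 to 118 ± 127.8 CPM, and MX1, a GTPase that blocks viruses (chromosome 21, 41420304 to 41459214), from 86.5 ± 59.0 to 820 ± 684 CPM, both higher in 8 of 8 pairs. IFI27 rose by 4.69 ± 0.63 (SE, adjusted p = 0.000777), and the interferon regulator IRF7 by 2.09 ± 0.25 (SE, adjusted p = 0.000686). Camera placed the list above the other genes (adjusted p = 1.966e-12), but not with an estimated correlation (adjusted p = 0.686 with an estimated correlation). After the GC and length correction the change was 1.78 ± 0.98 (SD).

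**Figure D2:**
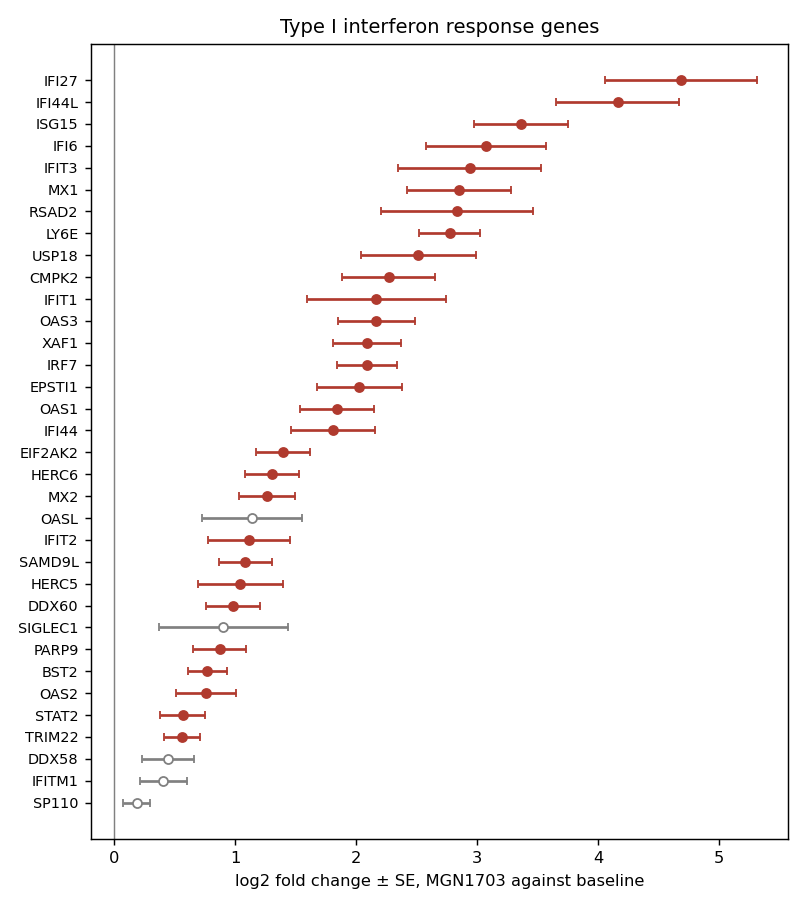
Log2 fold change, MGN1703 against baseline (x axis), with its standard error as bars, for 34 of the 35 tested genes of the type I interferon response list. Filled red points passed an adjusted p of 0.05 (29 genes) and open grey points did not (5 genes), and all 34 lie above 0.

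The interferon gamma response list did not pass as reported (0.39 ± 0.61, SD, n = 8 pairs, higher in 5 of 8, exact adjusted p = 0.27, camera adjusted p = 0.164), and passed the exact test when the median over members replaced the mean (0.72), and stood at 0.25 without replicate 8. Among its 15 tested members TAP1, the peptide transporter of antigen processing, CIITA, the master regulator of MHC class II, PSMB9, an immunoproteasome subunit, and ICAM1, an adhesion molecule, rose, and GBP2 fell. The same 4 and 1 passed when adjusted over the list alone. TAP1 had a log2 fold of 1.42 ± 0.23 (SE, adjusted p = 0.00128). CXCL10, an interferon-induced chemokine, had 1.26 ± 1.01 (SE, adjusted p = 0.355), with 0.60 without replicate 8, and passed by voom with quality weights (2.42). After the GC and length correction ICAM1 (0.12 ± 0.19, SE) and GBP2 (−0.26 ± 0.11, SE) did not pass.

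Genes of TLR9 signalling rose in 8 of 8 patients, by 0.60 ± 0.23 on the log2 scale (SD, exact adjusted p = 0.0313, camera adjusted p = 0.00594, and adjusted p = 0.686 with an estimated correlation). Of 22 tested members 11 rose, 1 fell and 10 did not pass, with 12 higher and 1 lower when adjusted over the list alone. Among those that rose was IRF7 (2.09 ± 0.25, SE), which is also in the type I interferon response list, so the lists are not fully separate results. MYD88, the adaptor that carries the TLR9 signal, went from 39.98 ± 14.8 to 124 ± 62.1 CPM (SD, n = 8), a log2 fold of 1.53 ± 0.19 (SE, adjusted p = 0.000686). CNPY3, a chaperone of Toll-like receptors, PLD3, a lysosomal nuclease, GRN, which encodes progranulin, and UNC93B1, which brings TLR9 to endosomes, rose by 1.15 ± 0.15, 1.33 ± 0.18, 1.43 ± 0.21 and 1.09 ± 0.25 (SE). TLR9 itself had 3.67 ± 3.25 CPM at baseline and 5.94 ± 4.99 after treatment (SD, n = 8), a log2 fold of 0.75 ± 0.93 (SE, adjusted p = 0.557), which ran from 0.30 to 1.31 when 1 pair was left out. After the GC and length correction TLR9 stood at 0.08 ± 0.96 (SE). The 1 member that fell was AP3B1, an adaptor of vesicle transport (−0.33 ± 0.09, SE, adjusted p = 0.0187). The members had a median GC content of 53.2%, and after the GC and length correction the change of the list was 0.37 ± 0.23 (SD), and 8 of 22 members passed. CNPY3 (0.66 ± 0.13), PLD3 (0.64 ± 0.18) and GRN (0.78 ± 0.20, SE) passed there with smaller folds, while AP3B1 (−0.08 ± 0.09, SE) and UNC93B1 (0.40 ± 0.23, SE) did not pass.

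Early targets of NF-kB rose in 8 of 8 patients by the exact test, by 0.49 ± 0.33 (SD, exact adjusted p = 0.0313), and did not pass camera (adjusted p = 0.117). Of 18 tested members 5 rose and 1 fell, against 4 and 1 when adjusted over the list alone. TNFAIP3, which ends NF-kB signalling, rose by 1.38 ± 0.28 (SE, adjusted p = 0.00336), the kinase MAP3K8 by 0.88 ± 0.21 (SE), the chemokine CCL3 by 0.72 ± 0.19 (SE), and ICAM1 and the activation marker CD83 rose too. BIRC3, an inhibitor of apoptosis that NF-kB induces, fell (−0.41 ± 0.10, SE, adjusted p = 0.0101), and was at −0.07 ± 0.11 (SE) after the GC and length correction. The call of the list ended without the block and when the median over members replaced the mean (0.20).

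The mean level of the pan B cell list rose in 8 of 8 patients, while some of its genes did not pass. The list went up by 0.60 ± 0.35 (SD, exact adjusted p = 0.0313, camera adjusted p = 0.00128, and adjusted p = 0.686 with an estimated correlation). Of its 17 members 10 rose, 0 fell and 7 did not pass, with 10 higher when adjusted over the list alone. PAX5, the transcription factor of B cell identity, rose by 0.87 ± 0.16, CD79B, a signalling chain of the B cell receptor, by 0.90 ± 0.17, and SPIB by 0.92 ± 0.19 (SE). MS4A1, which encodes CD20, had 0.12 ± 0.13 (SE, adjusted p = 0.527), and 0.03 without replicate 7. After the GC and length correction MS4A1 stood at 0.35 ± 0.12 (SE, adjusted p = 0.0524), just short of the threshold. The members had a median GC content of 56.4%, and after the GC and length correction the change of the list was 0.33 ± 0.32 (SD, higher in 7 of 8 pairs), which no longer passed the exact test, and 2 members passed. Camera still called the list there (adjusted p = 0.0455), but called 0 lists with that correction and an estimated correlation. The exact call also ended without the block and with the median over members (0.39). PAX5 (0.69 ± 0.16, SE) passed after that correction, while CD79B (0.37 ± 0.15, SE) and SPIB (0.46 ± 0.18, SE) did not.

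Genes of B cell receptor signalling rose by 0.42 ± 0.28 in 8 of 8 patients (SD, exact adjusted p = 0.0313, camera adjusted p = 0.0312, and adjusted p = 0.686 with an estimated correlation). Of 18 members 7 rose and 1 fell, against 7 and 2 when adjusted over the list alone. The kinase subunit PIK3CD rose by 0.99 ± 0.13, the exchange factor VAV1 by 0.84 ± 0.15 and the phospholipase PLCG2 by 0.93 ± 0.19 (SE), and the kinase PRKCB fell (−0.44 ± 0.11, SE). After the GC and length correction PIK3CD (0.50 ± 0.11) and VAV1 (0.38 ± 0.13) had smaller folds and PLCG2 (1.15 ± 0.20, SE) a larger one, and these passed. The exact call of the list ended with DESeq2's size factors (0.40), in thinned libraries (0.41), with mitochondrial genes left out (0.42), without the block and after the GC and length correction (0.35 ± 0.29, SD), where PRKCB (−0.23 ± 0.09, SE) did not pass either. The camera call ended without replicate 7 or 8 (0.34 and 0.42).

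Markers of naive B cells rose by 0.77 ± 0.56 (SD, higher in 7 of 8 pairs) by camera (adjusted p = 0.0269, and adjusted p = 0.686 with an estimated correlation), while the exact adjusted p was 0.0511. The list passed the exact test with library size alone (0.96) and without replicate 6 (0.93), the pair in which it fell (−0.40). Of 9 members 6 rose and 1 fell, and the same counts passed when adjusted over the list alone. The heavy chain genes IGHM (chromosome 14, 105851705 to 105856218) and IGHD, which naive B cells express together, rose by 1.48 ± 0.17 and 1.37 ± 0.22 (SE). After the GC and length correction these 2 genes stood at 0.93 ± 0.17 and 0.81 ± 0.20 (SE) and still passed. PLPP5 rose by 0.76 ± 0.13 and FCER2, the low-affinity IgE receptor CD23, by 1.02 ± 0.29 (SE), and FCMR, an Fc receptor for IgM, fell (−0.38 ± 0.11, SE). The camera call ended after the GC and length correction (0.44 ± 0.50, SD), where FCER2 (0.47 ± 0.25, SE) did not pass, and when immunoglobulin genes were left out (0.58) and without the block.

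Germinal centre B cell genes rose by 0.97 ± 1.45 by camera (SD, higher in 6 of 8 pairs, adjusted p = 0.0426, and adjusted p = 0.711 with an estimated correlation), and not by the exact test (exact adjusted p = 0.211). Of 16 tested members 4 rose and 12 did not pass, and 4 rose when adjusted over the list alone. They were NEIL1, a DNA repair glycosylase, at 2.15 ± 0.28, KLHL6 at 0.76 ± 0.19, BCL7A at 1.56 ± 0.45 and BCL6, the transcription factor of germinal centre cells, at 1.09 ± 0.37 (SE). CXCL13, the chemokine of B cell follicles, had 1.26 ± 0.87 (SE, adjusted p = 0.284), with 0.70 without replicate 7, and passed by voom with quality weights (2.47). BCL6 (1.11 ± 0.38, SE) and BCL7A (1.33 ± 0.46, SE) did not pass after the GC and length correction, and the camera call ended with library size alone (1.15), by fry, and when replicate 3, 7 or 8 was left out (0.83, 0.83 and 0.62).

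Proliferation genes rose by 1.06 ± 1.73 by camera (SD, higher in 5 of 8 pairs, adjusted p = 0.00128, and adjusted p = 0.711 with an estimated correlation), with an exact adjusted p of 0.228. Of 29 members 9 rose, 0 fell and 20 did not pass, and 9 rose when adjusted over the list alone. The replication licensing genes MCM5, MCM7 and MCM2 rose by 1.37 ± 0.20, 1.60 ± 0.29 and 1.80 ± 0.36 (SE), and RRM2, a ribonucleotide reductase subunit, by 2.14 ± 0.55 (SE). MKI67 had 0.68 ± 0.56 (SE, adjusted p = 0.368), which ran from 0.26 to 1.07 when 1 pair was left out, and passed by voom with quality weights (1.11). The list did not pass by fry, and stood at 0.68 without replicate 8.

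Plasma cell genes did not pass as a group (0.34 ± 0.55, SD, higher in 5 of 8 pairs, exact adjusted p = 0.232, camera adjusted p = 0.0607), and passed the exact test with library size alone (0.53). The list stood at 0.21 without replicate 6. Of 23 tested members 5 rose, over all genes and when adjusted over the list alone. They were POU2AF1, a B cell transcriptional co-activator (1.06 ± 0.18, SE), the surface enzyme CD38 (1.10 ± 0.24, SE), and PDIA4, HERPUD1 and DNAJB9, which serve protein folding and quality control in the endoplasmic reticulum. PRDM1, the regulator of plasma cell differentiation, had 0.25 ± 0.19 (SE, adjusted p = 0.339, but a call at 0.42 without replicate 1), XBP1 −0.19 ± 0.23 (adjusted p = 0.557), MZB1 0.61 ± 0.25 (adjusted p = 0.0773) and JCHAIN, the joining chain of IgM and IgA, −0.53 ± 0.41 (adjusted p = 0.342). MZB1 passed with library size alone (0.81), without replicate 4 (0.80) and in other alternatives, but stood at 0.13 ± 0.27 (SE, adjusted p = 0.76) after the GC and length correction. Leaving out replicate 2 took XBP1 to 0.01 and JCHAIN to −0.23. SDC1, the plasma cell marker CD138, and the T cell cytokine IL21 had too few counts to be tested, 64 and 53 over all baseline libraries.

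Immunoglobulin counts shifted away from IgG in most patients, without passing adjustment. IgG took 87.2% ± 6.78 of heavy chain constant counts at baseline and 69.3% ± 13.2 after treatment (SD, n = 8, lower in 7 of 8 pairs, exact p = 0.0234, adjusted p = 0.0625). IgA took 2.92% ± 1.28 and 6.62% ± 4.03 (higher in 8 of 8, exact p = 0.0078, adjusted p = 0.0625), IgM 8.91% ± 5.59 and 21.8% ± 12.8 (7 of 8, exact p = 0.0391, adjusted p = 0.0781) and IgD 0.936% ± 0.68 and 2.20% ± 1.41 (7 of 8, exact p = 0.0234, adjusted p = 0.0625). IgE took 0.0701% ± 0.0944 and 0.14% ± 0.198 (exact adjusted p = 0.396), and its difference ran from 0.00823 to 0.0895 when 1 pair was left out. Immunoglobulin genes took 2.19% ± 1.67 and 2.32% ± 1.82 of all counts (higher in 4 of 8 pairs, exact adjusted p = 0.883), kappa took 73.7% ± 6.42 and 71.9% ± 3.53 of light chain constant counts (exact adjusted p = 0.473), and the effective number of heavy chain variable genes was 24.8 ± 1.98 and 25.5 ± 2.15 (exact adjusted p = 0.338). Leaving out 1 pair took the difference in the immunoglobulin percent of all counts from −0.494 to 0.595, and that in the kappa percent from −3.10 to −0.608. Of the 8 measures 0 passed, against 4 at an unadjusted p under 0.05. The class percents are shares of 1 total, so the fall of IgG and the rises of the other classes are not separate results. Leaving out replicate 6 brought 4 measures, IgM, IgD, IgG and IgA, past the threshold (exact adjusted p = 0.0313). That pair holds 1 of the 2 libraries with over 15% mitochondrial ribosomal RNA, and its changes of several lists stood apart from those of the other pairs. The immunoglobulin constant list did not pass (0.34 ± 0.99, SD, higher in 4 of 8, exact adjusted p = 0.563, camera adjusted p = 0.34), and stood at 0.05 without replicate 6, in which it rose by 2.36. Its median fold (−0.08) and mean fold (0.30) differ in sign, and of its 14 members IGHM, IGHD and IGHA1 rose, over all genes and when adjusted over the list alone. IGHA1 had 1.24 ± 0.37 (SE, adjusted p = 0.0235) and 0.69 ± 0.37 (SE) after the GC and length correction, which ended its call, and IGHG1 had −0.20 ± 0.44 (SE, adjusted p = 0.751), from −0.57 to 0.05 when 1 pair was left out.

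**Figure D3:**
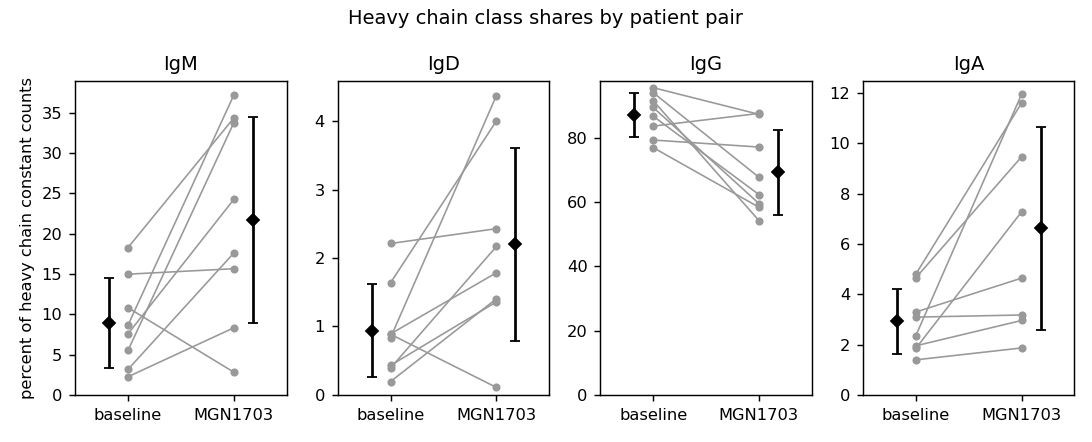
Percent of heavy chain constant counts (y axis) in IgM, IgD, IgG and IgA at baseline and after MGN1703. Grey lines join the 2 libraries of each of 8 patients, and black diamonds with bars are the mean ± SD, which for IgG are 87.2 ± 6.78 and 69.3 ± 13.2.

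The naive T cell list fell, and the pan T cell list did not pass. Markers of naive T cells fell by 0.44 on the log2 scale with an SD of 0.42 over 8 pairs by camera (lower in 7 of 8, adjusted p = 0.00652, and adjusted p = 0.686 with an estimated correlation), with an exact adjusted p of 0.075. Of 10 members 6 fell and 0 rose, over all genes and when adjusted over the list alone. LEF1, a transcription factor of naive T cells, fell from 349 ± 64.1 to 224 ± 46.1 CPM (SD, n = 8), and IL7R, the receptor of the survival cytokine interleukin 7, from 1113 ± 515 to 765 ± 310 CPM. LRRN3 fell by 0.91 and NELL2 by 0.66 on the log2 scale (SE 0.14 and 0.12). The pan T cell list did not pass (−0.23 ± 0.52, SD, exact adjusted p = 0.36, camera adjusted p = 0.0603) and stood at −0.12 without replicate 6 and −0.38 without replicate 2, while 6 of its 15 members fell, over all genes and when adjusted over the list alone, among them CD3G (−0.76 ± 0.11, SE), TRAT1 (−0.70 ± 0.10, SE) and TRAC (−0.67 ± 0.14, SE), parts or partners of the T cell receptor. The pan T cell list after the GC and length correction (−0.31 ± 0.50, SD) passed camera (adjusted p = 0.0029) and not the exact test (exact adjusted p = 0.211), and TRAC (−0.42 ± 0.14, SE) did not pass. Camera called 0 lists with that correction and an estimated correlation.

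The follicular helper T cell list, which names the T cells that help B cells in follicles, did not pass (0.12 ± 0.53, SD, exact adjusted p = 0.659, camera adjusted p = 0.587), ran from −0.01 to 0.23 when 1 pair was left out, and its members moved apart. Its mean fold (0.14) was above 0, and its median fold (−0.06) and camera's direction were below 0. PDCD1 (1.57 ± 0.43), CXCR5 (0.59 ± 0.19) and BCL6 (1.09 ± 0.37, SE) rose. CD40LG, the ligand through which T cells activate B cells (−0.96 ± 0.21), MAF (−0.99 ± 0.18), SH2D1A (−0.50 ± 0.10) and BTLA (−0.36 ± 0.11, SE) fell, which makes 3 higher and 4 lower of 13 tested members, over all genes and when adjusted over the list alone. After the GC and length correction PDCD1 (0.94 ± 0.43), CXCR5 (0.06 ± 0.18), SH2D1A (−0.25 ± 0.09) and BTLA (−0.09 ± 0.12, SE) did not pass, and CXCR5 missed the threshold in 6 of the 8 fits that left out 1 pair. B cells carry CXCR5, BCL6 and BTLA too.

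Conventional dendritic cell genes fell in 8 of 8 patients by the exact test (change −0.62 ± 0.60, SD, exact adjusted p = 0.0313), and did not pass camera (adjusted p = 0.101). The list fell by far the most in replicate 6 (−1.97), which holds a library that stood apart, and was at −0.43 without it, where it passed the exact test. Of 13 tested members 4 fell, over all genes and when adjusted over the list alone. FCER1A, the alpha chain of the high-affinity IgE receptor (chromosome 1, 159289714 to 159308224), went from 41.3 ± 51.6 to 14.1 ± 21.5 CPM (SD, n = 8), a log2 fold of −2.04 ± 0.28 (SE, adjusted p = 0.00078). Mast cells express FCER1A too, and the mast cell genes KIT (−1.39 ± 0.28), CPA3 (−1.66 ± 0.43), MS4A2 (−1.32 ± 0.44) and CMA1 (−1.99 ± 0.51, SE) also fell. CD207, the langerin of Langerhans cells, fell by 2.00, and the lipid-presenting molecules CD1E and CD1C by 1.32 and 0.80 on the log2 scale (SE 0.50, 0.33 and 0.21). The call of the list ended with scaling by library size alone (−0.44), without the block and with the median over members (−0.68), while after the GC and length correction (−0.59 ± 0.58, SD) the list passed both tests (exact adjusted p = 0.0469, camera adjusted p = 0.0229) and CD1C (−0.56 ± 0.21, SE) did not pass. With that correction and an estimated correlation camera called 0 lists. The plasmacytoid dendritic cell list did not pass (0.10 ± 0.66, SD, exact adjusted p = 0.782, camera adjusted p = 0.938), ran from −0.03 to 0.30 when 1 pair was left out, and its median (−0.11) and mean fold (0.14) differ in sign. Of its 9 tested members PLD4, a lysosomal nuclease shared with the TLR9 list, rose (0.97 ± 0.21, SE), as it did when adjusted over the list alone, but not after the GC and length correction (0.38 ± 0.20, SE). CLEC4C had −0.45 ± 0.30 (SE, adjusted p = 0.269), and −0.24 without replicate 6.

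Immediate early and heat shock genes, which also respond to the handling of tissue, rose in 8 of 8 patients by 1.35 ± 0.72 (SD, exact adjusted p = 0.0313, camera adjusted p = 7.3489e-05, and adjusted p = 0.686 with an estimated correlation). Of 19 tested members 12 rose, 0 fell and 7 did not pass, with 13 higher when adjusted over the list alone. FOS went from 140 ± 190 to 814 ± 928 CPM (SD, n = 8), and NR4A1 rose by 1.90 ± 0.25, ZFP36 by 1.70 ± 0.21 and the heat shock gene HSPA6 by 2.94 ± 0.47 (SE). The members had a median GC content of 57.3%, and after the GC and length correction the change was 1.01 ± 0.66 (SD), and the exact call ended with the median over members (1.31).

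Ribosomal protein genes fell in 8 of 8 patients (change −0.51 ± 0.28, SD, exact adjusted p = 0.0313, camera adjusted p = 7.4307e-16, and adjusted p = 0.686 with an estimated correlation). Of 79 tested members 58 fell, 2 rose and 19 did not pass, with 58 lower and 3 higher when adjusted over the list alone. RPL7 fell by 0.95, RPL5 by 0.90 and RPS4X by 0.84 on the log2 scale (SE 0.12, 0.12 and 0.10), and RPS15 (0.93 ± 0.12, SE) and RPL39L (1.40 ± 0.27, SE) rose. Within this list the fold rose with GC content (Spearman rho 0.63 across 79 genes). The exact call ended with scaling by library size alone (−0.32). Mitochondrially encoded genes fell by camera (change −1.26 ± 0.81, SD, lower in 7 of 8 pairs, adjusted p = 3.5898e-07, and adjusted p = 0.686 with an estimated correlation), with an exact adjusted p of 0.0511. The list passed the exact test with library size alone (−1.07) and without replicate 6 (−1.50), the pair in which it rose (0.42). All 13 members fell, over all genes and when adjusted over the list alone. MT-CO1, a subunit of cytochrome c oxidase, fell from 21104 ± 14578 to 7884.3 ± 4549.8 CPM (SD, n = 8), a log2 fold of −1.41 ± 0.18 (SE). After the GC and length correction the change was −0.83 ± 0.68 (SD).

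The blood endothelium list rose by 0.43 ± 0.47 in 8 of 8 patients by the exact test (SD, exact adjusted p = 0.0313) and not by camera (adjusted p = 0.702). It rests on 4 of 17 members, of which PLVAP, a protein of endothelial diaphragms, rose (1.55 ± 0.36, SE) and PECAM1, an adhesion molecule also found on leukocytes, fell (−0.43 ± 0.12, SE), against 2 higher and 1 lower when adjusted over the list alone. ENG had 0.88 ± 0.34 (adjusted p = 0.0661) and SELP −0.20 ± 0.27 (adjusted p = 0.589). ENG passed by limma-voom (1.04), DESeq2 (0.86) and in other alternatives, but stood at 0.20 ± 0.33 (SE) after the GC and length correction and did not pass. SELP stood at −0.43 without replicate 6 and −0.07 without replicate 5. After the GC and length correction the list was at 0.14 ± 0.51 (SD, higher in 4 of 8 pairs) and neither PLVAP nor PECAM1 passed. The call also ended without the block and with the median over members (0.34), and the list stood at 0.28 without replicate 6, in which it rose by 1.51.

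**Figure D4:**
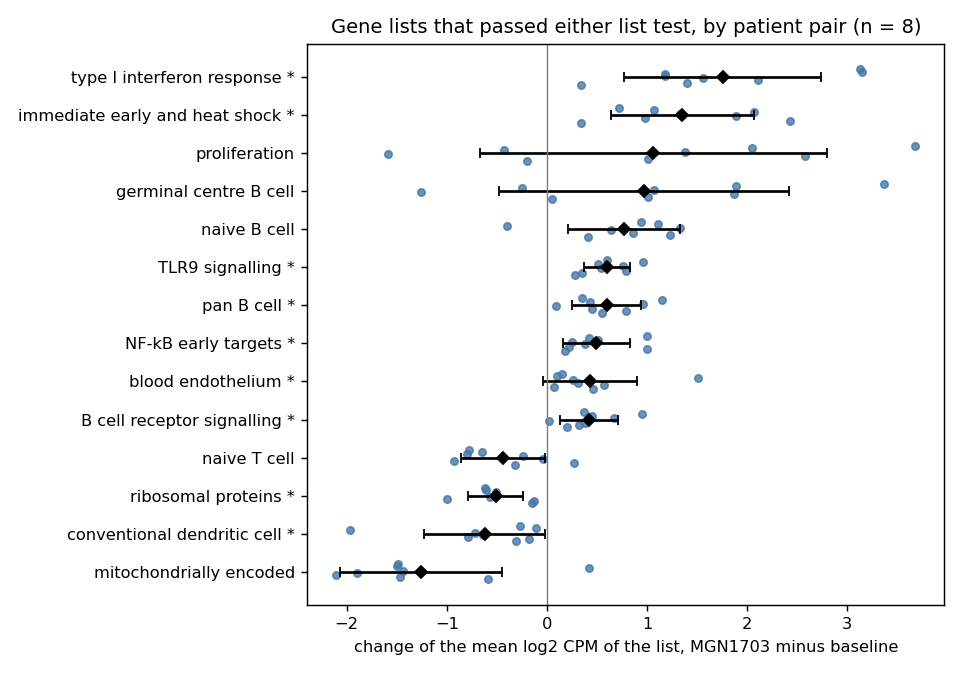
Change of the mean log2 CPM of each gene list that passed either list test (x axis, MGN1703 minus baseline), with 1 blue point per patient pair and black diamonds with bars for the mean ± SD of 8 pairs. An asterisk marks the 9 lists that passed the exact test, and the type I interferon response list, at 1.76 ± 0.98, lies above 0 in 8 of 8 pairs.

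In all, 11 of 36 lists passed camera, 8 higher and 3 lower, and 9 passed the exact test, 7 higher and 2 lower. With an estimated correlation 0 of the 11 camera calls held, and 0 lists had an unadjusted p under 0.05, against 13 lists past the threshold by fry. Camera called 14 lists after the GC and length correction, and 0 with an estimated correlation. Other splits of the libraries gave up to 20 lists by camera, and up to 21 where they parted all 8 pairs. Without replicate 6 the exact test called 12 lists, and without any other single pair 0, since 7 pairs allow no p below 0.0156. Across patients 3 relations between list changes were tested and 0 passed. The change of plasma cell genes was not shown to follow that of germinal centre B cell genes (Pearson r = 0.212, exact p = 0.624, adjusted p = 0.624, Spearman rho = 0.214, exact p = 0.619, adjusted p = 0.929, n = 8 pairs), with r = 0.838 without the 2 pairs farthest from the median. Plasma cell with type I interferon response genes gave r = 0.231 (exact p = 0.58, adjusted p = 0.624) and rho = −0.048 (exact p = 0.935, adjusted p = 0.935), with r = 0.58 without 2 pairs. Cytotoxic lymphocyte with type I interferon response genes gave r = 0.473 (exact p = 0.24, adjusted p = 0.624) and rho = 0.262 (exact p = 0.536, adjusted p = 0.929), with r = 0.438 without 2 pairs.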

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

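Apart from the relation within ribosomal protein genes and the comparison with other splits, the tests in this part were chosen, or rest on alternatives chosen, only after the results were seen.

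The type I interferon response list rose by 1.76 ± 0.98 (SD) in 8 of 8 pairs. It was at 1.78 after the GC and length correction, at 1.75 in libraries thinned to the smaller of each pair, and at 1.75 with mitochondrial genes left out. The first of these values argues against GC content and length bias as the whole cause. Leaving out mitochondrial genes could hardly test a few abundant genes as a cause, because the TMM factors already adjust for them in both fits. Thinning lowers the counts of all genes of a library alike, so it tests only the number of counts. It cannot test a difference in preparation that goes with the depth. A response to the TLR9 agonist may explain the rise, as a hypothesis. No untreated patients were sampled at both times, so an effect of time was not tested.

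The pan B cell list rose by 0.60 ± 0.35 (SD) in 8 of 8 pairs and stood at 0.334 ± 0.323 after the GC and length correction, higher in 7 of 8 pairs. There the exact call ended (exact adjusted p = 0.102, range over the alternatives 0.0304 to 0.196). The exact test gives its smallest p only where all 8 pairs move the same way. The camera call held there (adjusted p = 0.0455), but not with an estimated correlation. The change of 0.588 in thinned libraries speaks only to the number of counts, and a difference in preparation that goes with the depth was not tested. A larger share of B cells in the sampled tissue stays open: 15 of 17 members had a fold above 0 after the correction, but 2 of 17 passed, and 17 of 17 had one before it, so this count in part restates the rise. The rest of the change was removed with the trend that genes of like GC content and length share. As counted, the 1794 tested genes with 55 to 60% GC had a median fold of 0.517, and the list's median GC content was 56.4%. The removed part was thus not particular to B cell genes. Whether library bias or a biological shift gave the shared trend cannot be told apart. An effect of the treatment on B cells themselves stays open and was not tested.

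GC-rich genes were higher after treatment. The fold rose with GC content among ribosomal protein genes alone too (Spearman rho 0.63, permutation p = 1e-05, the smallest that 100000 resamples can give, 79 genes that are not independent replicates), as a GC content bias of the libraries would give. Such a bias may thus explain part of the folds. The relation stayed at rho 0.451 without the 2 pairs with much mitochondrial ribosomal RNA, which argues against those libraries as the cause. It stayed at rho 0.476 in thinned libraries, which speaks only to the number of counts and not to the preparation behind it. Treatment, time and any difference in library preparation go together in this design, so a biological shift towards GC-rich genes was not tested.

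Other splits of the 16 libraries were compared with the real 1, which gave 4463 changed genes, 2376 higher and 2087 lower. Of 100 splits 1, the real one, gave as many genes in each of these 3 counts, which is the smallest share that 100 splits can give. Of these splits 8, the real one among them, parted all 8 pairs. A pair that is not parted adds nothing to the group term in the fit with the block. The comparison cannot tell the treatment from other differences between the groups. The highest other split gave 3690 changed genes, 2078 in 1 direction and 1612 in the other. Since a split and its mirror are the same, 2078 was set against both directions. The split with 3690 exchanged 1 MGN1703 library for a baseline library and parted 6 of the 8 pairs. Of 100 splits that part all 8 pairs, 1 gave as many in each count, and the highest other gave 2308 changed, 1566 in 1 direction, set against both, and 742 in the other. For the 11 lists called by camera chance cannot be excluded: 54 of 100 splits, and 57 of 100 that part all 8 pairs, gave as many, with up to 20 and 21 lists. For the 9 lists called by the exact test 1 of 128 splits, the real one, gave as many, and the highest other gave 0. These 9 lists moved the same way in all 8 pairs, so a split that reverses some pairs cannot give them the smallest p. Since no list can pass unless at least 6 do, other splits had little way to call any, and this comparison adds no support of its own.

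In 22 of 428 groups of 8 values the highest or lowest value stood apart from the nearest other by more than Dixon's 95% critical value of the range, where chance gives about 1 in 20 groups, or 21.4. The total depth in the MGN1703 group had its highest value 0.591 of the range apart. At baseline the highest value stood apart for the mitochondrial mRNA share (0.5261), the fibroblast and reticular cell list (0.6), the lymphatic endothelium list (0.681) and KLRC1 (0.642). At baseline the lowest value stood apart for CD1E (0.648), XAF1 (0.544), SH2D1A (0.551), TNFSF13 (0.55), GNLY (0.649) and HDC (0.725). In the MGN1703 group the highest value stood apart for RPS4X (0.532), CSF3R (0.709), S100A9 (0.69), GZMK (0.634), FGFBP2 (0.613) and GZMA (0.62). In the MGN1703 group the lowest value stood apart for IRF7 (0.569), PDIA4 (0.58), CD74 (0.52615), GNLY (0.616) and PSMB9 (0.527).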

How the results depend on the processing

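The GC and length correction, the thinned libraries, the leaving out of 2 pairs or of mitochondrial genes, and the robust prior were chosen only after the results were seen.

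The number of changed genes, 4463, stayed within 1.5 times under other scalings, filters and tools (3615 to 5979), and fell to 1306 with no replicate block and to 2808 with the GC and length correction. Genes called both with and without each alternative had the same direction. With no replicate block 987 were higher and 319 lower, and 4 lists passed the exact test. Genes lower numbered 512 with library size alone, 1304 with no filter on low counts, where 27124 genes were tested, and 911 with the GC and length correction in the fit with the replicate block. Lists called by camera numbered 0 with an estimated inter-gene correlation, 0 with that and the GC and length correction, and 7 by fry after that correction. Camera with its preset correlation called 14 after it, with the pan T cell, conventional dendritic cell, neutrophil and blood monocyte and mast cell lists gained and the naive B cell list lost. Without the 2 pairs with over 15% mitochondrial ribosomal RNA 0 lists passed the exact test. Except for the block, which removes differences between patients, and the loss of pairs, the cause was not tested.

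Leaving out each pair in turn gave 3199 to 4502 changed genes, 1795 to 2415 higher and 1404 to 2087 lower. Camera called 9 to 14 lists. The exact test called 0 to 12 lists, 12 without replicate 6 and 0 without any other pair. With 7 pairs no p lies below 0.0156, and no list can then pass unless at least 12 do. The changes of replicate 6 lay outside those of the other 7 pairs for the neutrophil and blood monocyte (3.75), fibroblast (3.01), lymphatic endothelium (2.40), epithelium (−3.26), immunoglobulin constant (2.36) and macrophage (2.17) lists and other uncalled ones. They also did for the called lists of conventional dendritic cells (−1.97), blood endothelium (1.51), mitochondrially encoded genes (0.42) and naive B cells (−0.40), and its treated library held 18.5% mitochondrial ribosomal RNA. Immunoglobulin measures passing ran from 0 to 4, with 4 without replicate 6. Of 150 named genes that changed, 29 lost the call without at least 1 pair and 0 changed sign. CCL21, CD83, CXCR5, GZMK, ICAM1, SSPN and TSPAN7 lost it in 6 of 8 fits.

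Of 166 named genes, 120 kept direction and side of the threshold under the GC and length correction, 139 with library size alone and 78 with no replicate block. Under the other alternatives, apart from those that left out a single pair, at least 152 did.

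Named results that reversed were near 0 or did not pass as reported, except GNLY, a called gene (0.41) that stood at −0.15 with the GC and length correction. Of all 4463 changed genes, 105 had the opposite sign after that correction, none of them called there. That correction also reversed XBP1 (0.01), CD8A (−0.22) and the lists of immunoglobulin constant (−0.068), cytotoxic lymphocyte (−0.059) and plasmacytoid dendritic cell (−0.12) genes. Library size alone reversed XBP1 (0.0017), IGHG1 (0.011) and the lists of inhibitory receptors (0.11), macrophages (0.029) and fibroblasts (0.012). With no replicate block CD8A (−0.0255) and IGHG1 (0.18) reversed. The median over members reversed memory B cells (−0.0198) and fibroblasts (0.0777), DESeq2's size factors the cytotoxic list (−0.0020), and a prior count of 0.5 the B cell helper cytokines (−0.0021). Without the 2 pairs the cytotoxic list (−0.0261), the epithelium list (0.01) and the immunoglobulin percent of all counts (−0.0529) reversed. The cause was not tested.

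Leaving out 1 pair moved these results across 0: the immunoglobulin percent of all counts (−0.494 to 0.595), IGHG1 (−0.57 to 0.0482, above 0 without replicate 4), XBP1 (−0.36 to 0.0133, without replicate 2), and the lists of B cell helper cytokines (−0.0024 to 0.0870), cytotoxic lymphocytes (−0.0561 to 0.0632), epithelium (−0.46 to 0.20), fibroblasts (−0.61 to 0.18), follicular dendritic cells (−0.57 to 0.0768), follicular helper T cells (−0.0104 to 0.23), macrophages (−0.48 to 0.0481) and plasmacytoid dendritic cells (−0.0333 to 0.30). None of these passed its test with all 8 pairs.

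Thinning each pair to its smaller library gave 4446 changed genes, so the number of counts per library alone did not set that total. Depth limits genes with few counts, such as SDC1 and IL21, which could not be tested.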

Other observations

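No test in this part was chosen after its result was seen, apart from the GC and length correction, the thinned libraries and the naming of VCAM1 and CD14. The lists below passed neither list test as counted. After the GC and length correction the neutrophil and blood monocyte list (1.03 ± 1.33) and the mast cell list (−0.79 ± 1.18, SD) passed camera (adjusted p = 0.0318 for both) and not the exact test (exact adjusted p = 0.105 for both), and 0 lists passed with that correction and an estimated correlation. As counted, the neutrophil and blood monocyte list stood at 0.54 without replicate 6 and the mast cell list at −0.32 without replicate 3. The exact test called the memory B cell (0.39), MHC class II (0.42) and hypoxia (0.68) lists with library size alone, the hypoxia list in thinned libraries (0.59), the natural killer cell list with the median over members (−0.41) and the lymphatic endothelium list without replicate 6 (−2.44).

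Memory B cell genes moved by 0.21 ± 0.21 (SD, higher in 6 of 8 pairs, exact adjusted p = 0.075, camera adjusted p = 0.548). Of 14 members 4 rose and 2 fell, over all genes and when adjusted over the list alone. ITGAX, the integrin CD11c found on atypical memory B cells and myeloid cells, rose by 1.27 ± 0.21 and ZBTB32, a transcription factor of memory B cells, by 2.06 ± 0.37 (SE). TNFRSF13B, the receptor TACI (0.90 ± 0.17), and FCRL5 (0.56 ± 0.17) rose, while GPR183, which guides B cells to the follicle edge (−0.63 ± 0.20), and SSPN (−0.97 ± 0.35) fell, and these 4 did not pass after the GC and length correction (0.32, 0.54, −0.30 and −0.72). Class switch machinery moved by 0.39 ± 0.54 (SD, 5 of 8, exact adjusted p = 0.178, camera adjusted p = 0.808). Of 13 members 3 rose and 2 fell, against 4 and 2 when adjusted over the list alone. The uracil glycosylase UNG (1.01 ± 0.29) and MAD2L2 (1.24 ± 0.23), which with SHLD2 limits the trimming of DNA ends, were among those that rose. SHLD2 and the DNA ligase LIG4 fell. After the correction MAD2L2 (0.57), SHLD2 (−0.13) and LIG4 (−0.11) did not pass. B cell helper cytokines moved by 0.04 ± 0.21 (SD, 5 of 8, exact adjusted p = 0.69, camera adjusted p = 0.587), and by −0.0024 to 0.0870 when 1 pair was left out. Of 12 tested members TNFSF13, which encodes APRIL, and CD40 rose and CD40LG fell, over all genes and when adjusted over the list alone, and TNFSF13 (0.87 ± 0.15) did not pass after the correction (0.43 ± 0.15, SE).

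Regulatory T cell genes moved by −0.18 ± 0.46 (SD, lower in 5 of 8, exact adjusted p = 0.433, camera adjusted p = 0.0853), with −0.05 without replicate 6 and −0.28 without replicate 3. Of 10 tested members 6 fell and 1 rose, against 6 and 2 when adjusted over the list alone. The chemokine receptors CCR4 and CCR8 and the transcription factor IKZF2 fell (−1.31 ± 0.13, −0.76 ± 0.13 and −0.70 ± 0.10), and TNFRSF4, the costimulatory receptor OX40, rose (1.73 ± 0.35, SE). Cytotoxic lymphocyte genes moved by 0.02 ± 0.28 (SD, higher in 3 of 8, exact adjusted p = 0.844, camera adjusted p = 0.723), with a median fold of −0.04 and a mean fold of 0.02, and from −0.06 to 0.06 when 1 pair was left out. Of 20 members 4 rose and 4 fell, over all genes and when adjusted over the list alone. Perforin, PRF1 (1.29 ± 0.25), CST7, FGFBP2 and GNLY rose, and EOMES (−0.65 ± 0.14), KLRG1, GZMA and GZMK fell. After the correction GNLY (−0.15), KLRG1 (−0.35), GZMA (−0.12) and GZMK (−0.26) did not pass, and GZMB (−0.51 ± 0.29, SE, adjusted p = 0.197) and CD8A (0.16 ± 0.21, SE, adjusted p = 0.584) did not pass before it. GZMB passed without replicate 8 (−0.74) and stood at −0.28 without replicate 6, where CD8A stood at 0.05. Natural killer cell genes moved by −0.26 ± 0.30 (SD, lower in 6 of 8, exact adjusted p = 0.075, camera adjusted p = 0.108). The adaptor TYROBP (0.87 ± 0.27) rose and the receptor KLRC1 (−0.65 ± 0.18) fell, of 10 members over all genes and when adjusted over the list alone, neither of them after the correction (0.55 and −0.42). Inhibitory receptors moved by −0.07 ± 0.25 (SD, higher in 4 of 8, exact adjusted p = 0.613, camera adjusted p = 0.183), and stood at −0.02 without replicate 6 and −0.14 without replicate 8. LAG3 (1.45 ± 0.37) and PDCD1 rose and CD160 (−1.18 ± 0.18), CD244 (−0.76 ± 0.15) and BTLA fell, of 10 members over all genes and when adjusted over the list alone, LAG3 (0.80), PDCD1 (0.94) and BTLA (−0.09) not after the correction.

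Macrophage genes moved by −0.15 ± 1.18 (SD, higher in 4 of 8, exact adjusted p = 0.81, camera adjusted p = 0.737), and by −0.48 to 0.05 when 1 pair was left out. Of 19 members the lipopolysaccharide receptor CD14 rose (1.23 ± 0.43, but 0.79 ± 0.44 and not passing after the correction) and the mannose receptor MRC1 fell (−1.98 ± 0.47, SE), against 0 and 1 when adjusted over the list alone, and CD163 had −0.56 ± 0.59 (SE, adjusted p = 0.484), and −0.23 without replicate 2. Neutrophil and blood monocyte genes moved by 0.94 ± 1.33 (SD, 6 of 8, exact adjusted p = 0.109, camera adjusted p = 0.0603). Of 10 tested members FCN1 (1.28 ± 0.28), the growth factor receptor CSF3R (1.82 ± 0.43) and the alarmin S100A9 (1.01 ± 0.32, SE) rose, over all genes and when adjusted over the list alone. MHC class II genes moved by 0.23 ± 0.28 (SD, 6 of 8, exact adjusted p = 0.109, camera adjusted p = 0.25, and 0.15 without replicate 7), with HLA-DOA (0.81 ± 0.11) and the invariant chain CD74 (0.58 ± 0.16) higher of 8 members, over all genes and when adjusted over the list alone, and CD74 at 0.05 after the correction. Mast cell genes moved by −0.68 ± 1.18 (SD, lower in 6 of 8, exact adjusted p = 0.23, camera adjusted p = 0.127). Of 6 members KIT (−1.39 ± 0.28), the receptor of stem cell factor, CPA3, HDC and MS4A2 fell, over all genes and when adjusted over the list alone, and MS4A2 (−1.07 ± 0.44) did not pass after the correction. Hypoxia genes moved by 0.50 ± 0.46 (SD, 7 of 8, exact adjusted p = 0.0703, camera adjusted p = 0.12). Of 9 tested members DDIT4 (1.58 ± 0.27), the glucose transporter SLC2A1 (0.87 ± 0.17) and PFKFB3 (0.93 ± 0.23) rose and PDK1 (−0.83 ± 0.14) fell, over all genes and when adjusted over the list alone, PFKFB3 (0.56 ± 0.21, SE) not after the correction.

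Lymphatic endothelium genes moved by −1.83 ± 1.96 (SD, lower in 7 of 8, exact adjusted p = 0.0879, camera adjusted p = 0.106). Of 3 tested members LYVE1 (−3.09 ± 0.86) and CCL21 (−2.15 ± 0.76), a chemokine that draws T cells and dendritic cells into the node, fell, against 3 when adjusted over the list alone. Follicular dendritic cell genes moved by −0.27 ± 1.34 (SD, 4 of 8, exact adjusted p = 0.69, camera adjusted p = 0.442, and −0.57 to 0.08 when 1 pair was left out), with the adhesion molecule VCAM1 (−1.36 ± 0.43) lower of 7 members, 0 when adjusted over the list alone, and not after the correction (−1.05 ± 0.41, SE). Fibroblast and reticular cell genes moved by −0.16 ± 1.43 (SD, lower in 6 of 8, exact adjusted p = 0.827, camera adjusted p = 0.808), and by −0.61 to 0.18 when 1 pair was left out. By edgeR 0 of 9 tested members passed, over all genes or when adjusted over the list alone. Epithelium genes moved by −0.23 ± 1.31 (SD, higher in 5 of 8, exact adjusted p = 0.844, camera adjusted p = 0.808, with camera's direction up, and −0.46 to 0.20 when 1 pair was left out), and of 3 tested members the keratin KRT18 rose (1.29 ± 0.29, SE), over all genes and when adjusted over the list alone. The adipocyte, red cell, platelet and skeletal muscle lists had under 3 tested members and were not tested.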
